A study of Mus musculus with 3 samples.

How the data were processed

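DNA methylation was measured by MBD-seq, in which a methyl-CpG-binding domain protein pulls down methylated DNA fragments before sequencing, in 3 libraries of mouse proximal colon organoids. The organoids carried a Braf V600E allele that Cre recombinase switches on. Per the labels, 1 library came from organoids that had received an empty lentiviral backbone (EV) and stayed in full medium, 1 from organoids with activated Braf in full medium, and 1 from organoids with activated Braf selected to grow in Base medium, which lacks the niche factors that intestinal stem cells depend on. All had been cultured for 5 months and then grown for 3 weeks. Each group held 1 library, so no difference below has a replicate check and no p-value is given.

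Per the labels' protocols, 100 to 200 ng of DNA was sheared to fragments of 200 to 400 bp and sequenced as single reads of 50 bp. Bowtie2 and mm10 are named in the submitters' processing notes, without a version; the step that gave values per bin is not given in the sources used here. The deposited table holds log2 values made by the authors for 12313737 bins of 200 bp on chromosomes 1 to 19. Chromosomes X and Y were not analysed here. Raising 2 to the deposited log2 value gave, in every bin of every library, a shared floor of 0.0153 plus a whole number of steps, within a tolerance of 0.001 of a step. The step was 0.0502 in the EV library, 0.0490 in the Braf full medium library and 0.0370 in the Braf Base medium library. The whole numbers were taken as read overlaps per bin, and overlaps times the step, without the floor, as normalised coverage.

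Total overlaps were 12530155 in the EV library, 20914446 in the Braf full medium library and 14850571 in the Braf Base medium library. Isolated runs of bins with 1 overlap each were taken as lone reads; in the same order 49.6%, 50.5% and 49.2% of them covered 2 bins and 46.8%, 36.3% and 45.6% covered 3. The averages over runs of 2 or 3 bins, 2.49, 2.42 and 2.48, put the libraries at an estimated 5041726, 8648828 and 5985362 reads; other runs were left out. The library size implied by the step was 1.59, 0.976 and 1.82 times the total overlaps. The authors' scaling was thus proportional neither to these overlaps nor to the reads estimated here. Whether it followed all sequenced or mapped reads cannot be checked here. Intervals of a coverage ratio are exact binomial (Clopper-Pearson) 95% intervals on estimated reads. They cover counting error only and compare 2 libraries, not 2 conditions. A fold against a library with 0 overlaps is a lower bound, taken against 3 reads in that library's window.

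The gene table used was built on GRCm38.p6, the assembly that mm10 stands for. It gives no strand, no transcript starts and no CpG islands. The design fixed before the data were examined called for windows at transcription start sites with a CpG island. In its place, coverage was averaged over windows reaching 1 kb to each side of both ends of 20661 protein-coding genes, which made 41322 gene ends, named low and high after their coordinate. The CpG island condition was dropped, also in matching the random lists. For a gene on the forward strand the low end is the start, and for a gene on the reverse strand the high end is.

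A gene end was called gained where the log2 ratio of 2 libraries, each with a pseudocount of 0.0597 added, was at least 1, and lost where it was at most -1, if the higher library also reached a coverage of 0.119. The pseudocount is the mean coverage per bin over the 3 libraries and the minimum is 2 times that mean. Log2 ratios are on this scale and understate the change of low windows, while folds are plain ratios of coverage. A gene counts as gained or lost if either end does. Scaling the libraries to equal totals would shift the log2 coverage of every bin, relative to EV, by -0.70 in the Braf full medium library and 0.19 in the Braf Base medium library. Scaling to an equal median of covered windows would shift it by -0.29 and -0.13.

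The rule for named genes, fixed before the data were examined apart from its start-site and CpG island terms, took per comparison the 10 largest gains and 10 largest losses, up to 4 called members of each of 19 gene lists, and always a short set of genes that included Cdx2, Sfrp4, Sox17, Cdkn2a, Igfbp7 and Braf. A few genes that the rule chose are not reported here by name; they stay in all counts of genes and lists. Genes whose windows overlapped were named together. The lists covered Wnt antagonists, Wnt ligands, intestinal transcription factors, colonic differentiation genes, intestinal stem cell genes, fetal-like and gastric genes, tumour suppressor and senescence genes, mouse orthologs of human CpG island methylator panels, MAPK feedback and output genes, BMP and TGF-beta genes, Hox genes, other developmental transcription factors, germline genes, imprinted genes, housekeeping genes, and markers of colon epithelium, fibroblasts and smooth muscle, immune cells, and endothelial and neural cells. A list's median log2 ratio was ranked among 10000 random lists of the same size matched on mean coverage, as a description of these libraries.

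Simulated counts came from 20 sets of libraries that shared 1 methylation profile and differed only in background, depth, scaling and counting noise. They hold no variation between cultures or library preparations and no copy number shifts, so they are not rates of false calls. The calling step was also tested on gains added to simulated data that held 41322 gene ends. With Braf Base medium against EV, it recovered 28% of 2-fold, 92% of 4-fold and 100% of 8-fold gains. For Braf full medium against EV it recovered 44% of 2-fold and 100% of 4-fold gains. For Braf Base medium against Braf full medium it recovered 16% of 2-fold and 78% of 4-fold gains. These percentages are shares of the added gains and cannot be read as recovery over all 41322 ends. Median coverage over all gene ends was 0.00913 in EV, and an 8-fold gain from there stays below the minimum of 0.119. Recovery at ends with such low coverage is thus not described by this test. Background coverage, used in place of relative DNA dosage, was read from bins with few overlaps, averaged over segments of 5 Mb; that it follows dosage was not tested. Alternatives covered the scaling, the pseudocount, the window, the minimum, the size of change, background subtraction, dosage, the mean over both gene ends, gene length and counting intervals; background subtraction, dosage, the mean over both ends, gene length and counting intervals were chosen after seeing the data. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.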

Results

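Methylated DNA was profiled in 3 organoid libraries, 1 for each of EV in full medium, Braf in full medium and Braf in Base medium. EV is the lentiviral backbone without Cre, and Base medium leaves out the stem-cell niche factors. The Braf full medium library differed from the others in its background. No read fell in 87.2% of the 200-bp bins of the EV library and in 83.0% of those of the Braf Base medium library, but in only 43.3% of those of the Braf full medium library. Median coverage over all gene ends was 0.00913 in EV, 0.0579 in Braf full medium and 0.00674 in Braf Base medium. Bins grouped in covered 1-kb tiles held 88.3%, 55.0% and 84.8% of the coverage in the same order.

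**Figure D1:**
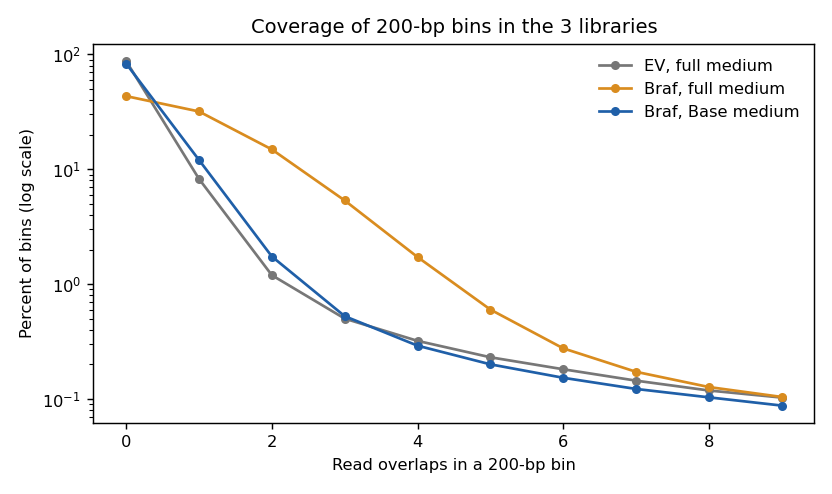
Percent of 200-bp bins (log scale) with each number of read overlaps in the EV, Braf full medium and Braf Base medium libraries. Bins with 0 overlaps made up 87.2%, 43.3% and 83.0%, and the Braf full medium library lay above the others from 1 to 9 overlaps.

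Activation of Braf in full medium, the first comparison, addresses what the oncogene goes with after long culture. Cdx1, a homeobox transcription factor of the intestinal epithelium, had no overlap at its high end on chromosome 18 in EV and a coverage of 1.31 in Braf full medium, at least 38.4-fold higher. Ends of developmental regulators gained coverage with it: Hand1, a factor of heart and neural crest development, rose from 0.00913 to 0.927 and Hoxa6 from 0.0183 to 1.10. Sox17, an antagonist of Wnt signalling and an endoderm factor, rose from 0.0137 to 0.423 at its low end and from 0.0274 to 0.503 at its high end. In all, 1766 genes gained coverage at an end and 234 lost it.

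The largest gain was at the low end of Tmem150a on chromosome 6, from 0 to 1.67, at least 49.2-fold. H2-DMa, which helps load peptides on MHC class II, rose from 0.0867 to 3.98 on chromosome 17 (45.9-fold, 95% interval 22.0 to 102). Spata32 rose from 0.0228 to 1.90 and Map3k14, whose window overlaps its own, from 0 to 0.165. B4galt2, a galactosyltransferase, rose from 0.0502 to 2.48, and its neighbour Atp6v0b, a subunit of the vacuolar proton pump, from 0 to 1.28. The predicted gene Gm52351 shares the Cdx1 window. Ogfod2 rose from 0.0319 to 1.99, and Nid1, a basement membrane protein, from 0.0365 to 1.92. The neighbours Med9, a Mediator subunit, and Rasd1, a small GTPase, reached 1.25 and 1.17 from 0. Slc22a21, a carnitine transporter, rose from 0.0274 to 1.74, and the zinc finger gene Zfp37 from 0 to 1.15.

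The largest loss was at the low end of Mpped2 on chromosome 2, from 2.51 in EV to 0.0802 (31.2-fold lower). Ranbp17, a nuclear transport receptor, fell from 0.872 to 0.0401. Mlh3, a DNA mismatch repair gene, fell from 1.01 to 0.0624 at its high end on chromosome 12. Fam32a fell from 0.922 to 0.0668, and Pop5, a subunit of RNase P, from 1.39 to 0.134. The neighbours Eef1d, an elongation factor subunit, and Tigd5 both fell from 0.917 to 0.0713. Vtn, which encodes vitronectin, fell from 0.872 to 0.0668, Glyctk, a glycerate kinase, from 0.817 to 0.0624, and Disp3 from 0.438 to 0.0134. Kcnab2, a potassium channel subunit, and its neighbour Nphp4 went from 0.374 and 0.178 to 0. These 3 lie on distal chromosome 4, where background coverage of full medium relative to EV was also lower than elsewhere, and most so in the segment from 150 Mb that holds Kcnab2 and Nphp4 (log2 ratio of EV over full medium 1.68, of Base over full medium 0.96). With local dosage divided out, the log2 ratios of Disp3, Kcnab2 and Nphp4 moved from -2.77, -2.86 and -1.99 to -2.26, -2.19 and -1.43.

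**Figure D2:**
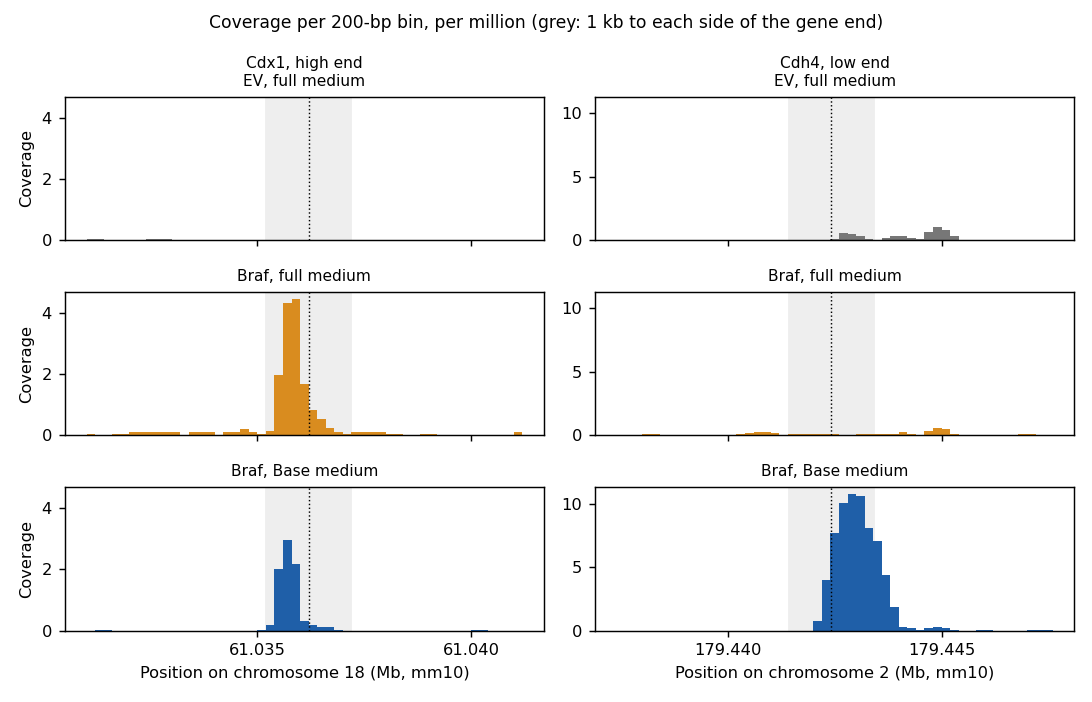
Normalised coverage per 200-bp bin within about 5 kb of the high end of Cdx1 and the low end of Cdh4 (dotted lines; mm10 positions) in each of the 3 libraries. Near Cdx1 the highest bin was at 0.0502 in EV, 4.46 in Braf full medium and 2.96 in Braf Base medium; near Cdh4 it was at 1.0, 0.588 and 10.7.

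Among the fixed lists, developmental transcription factors outside the Hox clusters stood out, with 51 of 119 gained and 3 lost, where 10.2 would be gained if they behaved as all genes did. Besides Hand1, the examples were Tlx2 (0.0411 to 1.22), Pax2 (0 to 0.641) and Hand2 (0.0183 to 0.650). Their median log2 ratio of 0.85 lay above all random lists (percentile 100), and stayed there, at 0.30, with background subtracted. Of 39 Hox genes, 9 gained, among them Hoxc11 (0 to 0.579) and Hoxd1 (0.00456 to 0.236), and 2 lost, among them Hoxd3 (0.534 to 0.0624). Of 31 Wnt antagonists, 8 gained and 0 lost; beside Sox17 these included Sfrp2 (0 to 0.330), Shisa3 (0.0593 to 0.619) and Nkd1 (0.00913 to 0.20). Of 18 Wnt ligands, 6 gained, among them Wnt5a (0 to 0.214), Wnt16 (0.0183 to 0.192), Wnt4 (0.0319 to 0.205) and Wnt3 (0.0228 to 0.178). Of 34 BMP and TGF-beta genes, 8 gained, led by Bmpr1b (0.0456 to 0.895), Gdf7 (0 to 0.258), Tgfbr3 (0.0137 to 0.192) and Bmp4 (0.242 to 0.913). At the 8.55% of all genes, 3.33 Hox genes, 2.65 Wnt antagonists, 1.54 Wnt ligands and 2.91 BMP and TGF-beta genes would have gained. In the same order, the median log2 ratios of these lists were at percentiles 40.7, 63.0, 90.4 and 84.9 of the random lists.

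Of 30 intestinal transcription factors, 8 gained and 1 lost. Beside Cdx1, Gata5 rose from 0.0821 to 0.668, Gfi1, a factor of secretory cells, from 0.0365 to 0.276, and Creb3l1 from 0.00456 to 0.125. Cdx2 had no overlap in EV and 0.0757 and 0.0891 at its low and high ends in Braf full medium, below the minimum for a call. Of 27 methylator panel orthologs, 6 gained and 1 lost; Fbn2 rose from 0.0958 to 0.699, Socs1 from 0.146 to 0.780 and Vim from 0.0319 to 0.294. Of 29 tumour suppressor and senescence genes, 5 gained and 1 lost. Cdkn2a encodes p16 and p19, but windows at its separate transcript starts were planned and not measured. Its low end rose from 0.0183 to 0.205 and its high end from 0.0730 to 0.236. Timp3 rose from 0.780 to 2.33 and Dapk1 from 0.648 to 1.87. Cdkn2b rose from 0 to 0.120. That value, like the 0.125 of Creb3l1, lay close to the minimum of 0.119 for a call. The median over all gene ends was 0.0579 in Braf full medium. The Cdkn2a high end kept a log2 ratio of only 0.94 with background subtracted and 0.66 with equal totals. Igfbp7 had 0.648 and 1.13 at its high end, Sfrp4 0.00913 and 0.0668 at its low end, and Braf 0 and 0.0624 at its high end, and none of these was called. At the share of all genes, 2.56 intestinal transcription factors, 2.31 methylator panel orthologs and 2.48 tumour suppressor and senescence genes would have gained. The median log2 ratios of these lists were at percentiles 85.5, 83.2 and 72.0 of the random lists. With background subtracted the percentiles were 99.7, 37.7 and 35.5.

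Smaller numbers were called elsewhere. Of 18 stem cell genes, 3 gained (Tert from 0 to 0.192, Ascl2 from 0.00913 to 0.143, Lrig1 from 0.0456 to 0.151) and Hopx was lost (0.224 to 0.0223). Of 14 fetal-like and gastric genes, 3 gained (Anxa10 from 0 to 0.125, Sox2 from 0.132 to 0.472, Muc5ac from 0.0137 to 0.134) and 1 was lost. Of 28 colonic differentiation genes, 2 gained, Chga (0.0137 to 0.321) and Alpi (0.0319 to 0.249), and of 27 MAPK genes, 1 gained, Dusp2 (0 to 0.192). Of 15 imprinted genes, Grb10 (0.219 to 1.20) and Impact (0.0183 to 0.138) gained, and of 27 germline genes Piwil1 was lost (0.634 to 0.205). Of 30 housekeeping genes 2 gained, among them Actb (0 to 0.147). Anxa10, Muc5ac, Impact, Ascl2 and Actb thus reached only 0.125 to 0.147, near the minimum of 0.119 for a call. Of the cell type markers, Cldn3 gained among 16 of epithelium, Vim, Zeb2 (0 to 0.134) and Tagln (0.251 to 0.610) gained and Col1a1 (0.397 to 0.0713) was lost among 16 of fibroblasts and smooth muscle, and Sox10, Kdr and Elavl3 gained among 13 of endothelial and neural cells. None of 16 immune markers was called. Of all genes 8.55% gained. Below that share lay colonic differentiation (7.14%), housekeeping (6.67%) and MAPK genes (3.70%), epithelial markers (6.25%), and the germline genes and immune markers, of which none gained. Above it lay stem cell (16.7%), fetal-like and gastric (21.4%) and imprinted genes (13.3%). Markers of fibroblasts and smooth muscle (18.8%) and of endothelial and neural cells (23.1%) also lay above it.

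Simulated libraries that differed in background and depth but not in methylation gave a median of 1294 genes gained and 1 lost. With background subtracted, 954 genes gained and 527 lost, against 56.5 and 75.5 simulated, and with equal totals 787 gained and 884 lost. Lists changed with these settings. With equal totals, tumour suppressor and senescence genes had 1 gained and 3 lost, intestinal transcription factors 3 and 1, fetal-like and gastric genes 0 and 1, stem cell genes 1 and 1, MAPK genes 1 and 3, germline genes 0 and 6, and endothelial and neural markers 2 and 3. BMP and TGF-beta genes had 4 gained and 1 lost, methylator panel orthologs 4 and 3, Hox genes 8 and 5, Wnt antagonists 6 and 0, Wnt ligands 4 and 0, and no housekeeping gene was called. With background subtracted, tumour suppressor and senescence genes had 3 gained and 2 lost, intestinal transcription factors 4 and 1, fetal-like and gastric genes 1 and 1, stem cell genes 1 and 1, BMP and TGF-beta genes 5 and 1, and methylator panel orthologs 5 and 2. No Wnt ligand gained with a minimum of 5 times the mean or with a pseudocount 4 times as large, and 2 did with the mean over both ends. Epithelial markers had 0 gained and 1 lost under both settings, and the log2 ratio at Cldn3 fell from 1.16 to 0.79. Developmental transcription factors outside the Hox clusters had 35 gained and 7 lost with equal totals and 40 and 6 with background subtracted.

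Growth without niche factors was read from Braf organoids in Base medium against those in full medium. Cdh4, which encodes R-cadherin and is silenced in human gastrointestinal cancers, rose at its low end on chromosome 2 from 0.102 to 5.37 (52.4-fold, 95% interval 28.2 to 118). The developmental factors Irx1 (0.143 to 1.86) and Msx2 (0.410 to 2.81) also gained. Hoxb2 went the other way at its high end on chromosome 11, from 1.89 to 0, at least 75.2-fold lower. In all, 417 genes gained and 1115 lost.

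After Cdh4, the largest gains were at Cdyl2, a chromodomain gene (0.0267 to 2.82), the adhesion receptor gene Adgrl2 (0.0935 to 4.35), the kinase gene Mast4 (0.0445 to 2.44) and the transporter gene Slco3a1 (0.0401 to 2.30). The cell adhesion genes Sdk2 (0.178 to 4.37) and Sdk1 (0.116 to 3.05) followed, with Dmrta2 (0.107 to 2.85), Syt9 (0.0668 to 2.05) and Gas1, a hedgehog co-receptor (0.129 to 3.05). After Hoxb2, the largest losses included those at Slc22a21 (1.74 to 0), Cfap300 (1.11 to 0), 4930444P10Rik (1.39 to 0.0337), Dmrta1 (1.02 to 0.0202) and Wdr31 (0.833 to 0.0101). Hs6st3 fell from 1.79 to 0.111 and Uggt2 from 0.984 to 0.0370, both near 119 Mb on chromosome 14, in a segment where the background of the Base medium library was also low. Gm51571 fell from 0.575 to 0.00674.

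Developmental transcription factors outside the Hox clusters had 28 of 119 genes gained and 13 lost, against 2.40 and 6.42 if they behaved as all genes did; Nkx3-2 (0.325 to 0.00674) and the high end of Tlx2 (0.508 to 0.0404) were among the losses. Of the Hox genes, 5 gained, among them Hoxd1 (0.236 to 2.08), Hoxa4 (0.0980 to 0.892) and Hoxd13 (0.303 to 1.19), and 2 lost. Of the methylator panel orthologs 4 gained and 2 lost: Fbn2 rose further, from 0.699 to 3.85, and Eya4 from 0.116 to 0.872, while Igf2 fell from 0.281 to 0.0135. Frzb (0.111 to 0.576), Sfrp1 (0.463 to 1.02) and Notum (0.864 to 1.84) were the 3 Wnt antagonists gained, and Kremen2 (1.46 to 0.663) the 1 lost. Of the BMP and TGF-beta genes, 2 gained, among them Gdf7 (0.298 to 1.67 at its low end), and Grem1 (0.147 to 0.0337) was lost. Spry4 (0.0624 to 0.290) was the 1 MAPK gene gained, Car4 (0.0401 to 0.242) the 1 colonic differentiation gene, and Grb10 (1.20 to 3.13) the 1 imprinted gene.

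In the other lists, Wnt10a (0.125 to 0.00337) and Wnt7a (0.120 to 0.0101), Creb3l1 (0.125 to 0), Gfi1 (0.276 to 0.0505), Spdef (0.125 to 0.0101), Neurod1 (0.134 to 0.0269), Ascl2 (0.143 to 0.0168), Muc5ac (0.134 to 0), Anxa10 (0.125 to 0.0101), Cdkn2b (0.120 to 0.00337) and Hic1 (0.129 to 0.0303) were lost, as were 2 housekeeping genes, among them Actb (0.147 to 0.0135). All the genes just named except Gfi1 started from 0.120 to 0.147, near the minimum of 0.119 for a call. The median over all gene ends was 0.0579 in Braf full medium. Chga, Alpi, Impact, Cldn3 and Tagln, gained in the first comparison, were lost in this one, while Elavl4 and Kdr gained. No germline or immune gene was called with the scaling as deposited. Sox17 had 0.423 and 0.802 at its low end, Sfrp4 0.0668 and 0.192, Cdkn2a 0.236 and 0.239 at its high end, Igfbp7 1.13 and 1.78, and Cdx2 0.0757 and 0 at its low end, all short of a call, as was Braf (0.0624 and 0.0135 at its high end). The log2 ratios of 0.99 at Sfrp4, 0.83 at Sox17 and 0.64 at Igfbp7 became 1.84, 1.01 and 0.70 with background subtracted and 1.55, 1.64 and 1.49 with equal totals.

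Simulated libraries with no difference in methylation gave a median of 0 genes gained and 1324.5 lost here. The balance turned with background subtracted, to 695 gained and 341 lost, and with equal totals, to 1972 gained and 205 lost. It also turned with a minimum of 5 times the mean, to 352 and 222, and with a pseudocount 4 times as large, to 239 and 119. With equal totals, 13 of 27 germline genes and 9 of 15 imprinted genes gained and 0 of either list lost, while intestinal transcription factors had 3 gained and 1 lost and tumour suppressor and senescence genes 6 and 0. No Wnt ligand, stem cell, fetal-like and gastric, housekeeping or tumour suppressor and senescence gene and no epithelial marker was lost with equal totals or with background subtracted. Developmental transcription factors outside the Hox clusters had 52 gained and 3 lost with equal totals and 39 and 6 with background subtracted. Hox genes gained were 14 and 9 under these settings, BMP and TGF-beta genes 8 and 4, Wnt antagonists 7 and 5, and methylator panel orthologs 8 and 6.

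Braf Base medium against EV spans both steps and sets the libraries with low background side by side. Developmental regulators gained coverage widely: Msx2 rose from 0.0274 to 2.81 (103-fold, 95% interval 34.1 to 1028), Twist1, a mesoderm factor, from 0.0639 to 3.04, and Hoxd1 from 0.00456 to 2.08. The Wnt antagonists Sox17 (0.0137 to 0.802) and Sfrp1 (0.114 to 1.02) gained too, and Hoxb2 lost all of its 0.867 at the high end. In all, 1279 genes gained and 540 lost, where simulated libraries with no difference in methylation gave medians of 15 and 19. Those libraries hold no variation between cultures or preparations, so 15 and 19 are not rates of false calls.

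The largest gain was at the high end of Adgrl2 on chromosome 3, from 0.00913 to 4.35 (477-fold, 95% interval 68.6 to 15187), in a segment where background coverage was also higher in Base medium. Mdga2, a neural adhesion gene, rose from 0.0183 to 4.04, and Satb1, which organises chromatin loops, from 0 to 2.59. Cdyl2 rose from 0 to 2.82, the phosphatase gene Ptprm from 0.0684 to 4.99, Slc2a13, a myo-inositol transporter, from 0 to 2.24, Tmem132c from 0.0319 to 3.42 and the scaffold gene Grip1 from 0.00913 to 2.31. Tmem150a and H2-DMa, the leading gains of the first comparison, stood at 2.23 and 5.30. The largest losses were at Fam32a (0.922 to 0), Eef1d and Tigd5 (both 0.917 to 0), Hoxb2, Ranbp17 (0.872 to 0.0135), Glyctk (0.817 to 0.0101), Tnfrsf23, a decoy receptor (0.675 to 0), Mlh3 (1.01 to 0.0303), the calcium channel gene Cacna1a (0.904 to 0.0269) and the stress gene Gadd45b (0.625 to 0.00337).

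**Figure D3:**
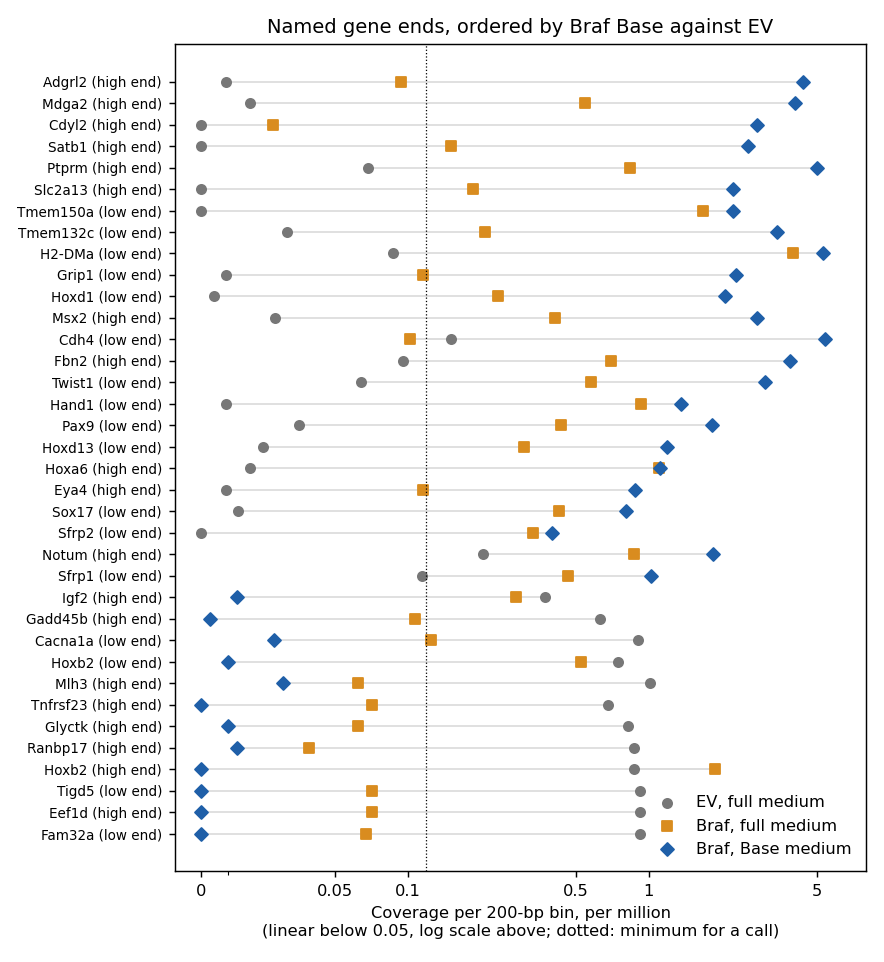
Normalised coverage per 200-bp bin (linear below 0.05, log scale above), of named gene ends in the 3 libraries, 1 point per library. At Cdh4 and Adgrl2 the Braf full medium point stayed near 0.1 and the Base medium point reached 5.37 and 4.35; at Fam32a, Ranbp17 and Mlh3 both Braf points lay below EV.

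Over all genes 6.19% gained and 2.61% lost. Of the 119 developmental transcription factors outside the Hox clusters, 60 gained and 5 lost, where 7.37 and 3.11 would be expected if they behaved as all genes did. Hand1 (0.00913 to 1.36) and Pax9 (0.0365 to 1.82) were further examples. Their median log2 ratio was 0.65, above all 10000 random lists. Of 39 Hox genes 12 gained, among them Hoxd13 (0.0228 to 1.19) and Hoxa6 (0.0183 to 1.11), and 5 lost. Of 27 methylator panel orthologs 9 gained, led by Cdh4 (0.151 to 5.37), Fbn2 (0.0958 to 3.85) and Eya4 (0.00913 to 0.872), and 2 lost, among them Igf2 (0.370 to 0.0135). Of 31 Wnt antagonists 8 gained and 0 lost, among them Notum (0.205 to 1.84) and Sfrp2 (0 to 0.397). Of 18 Wnt ligands 5 gained, including Wnt4 (0.0319 to 0.317), Wnt5a (0 to 0.162), Wnt3 (0.0228 to 0.242) and Wnt5b (0.0137 to 0.168), and of 34 BMP and TGF-beta genes 6 gained, including Bmpr1b (0.0456 to 1.69, on the same segment of chromosome 3 as Adgrl2), Gdf7 (0 to 0.310), Tgfbr3 (0.0137 to 0.273) and Gdf6 (0.0183 to 0.276).

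**Figure D4:**
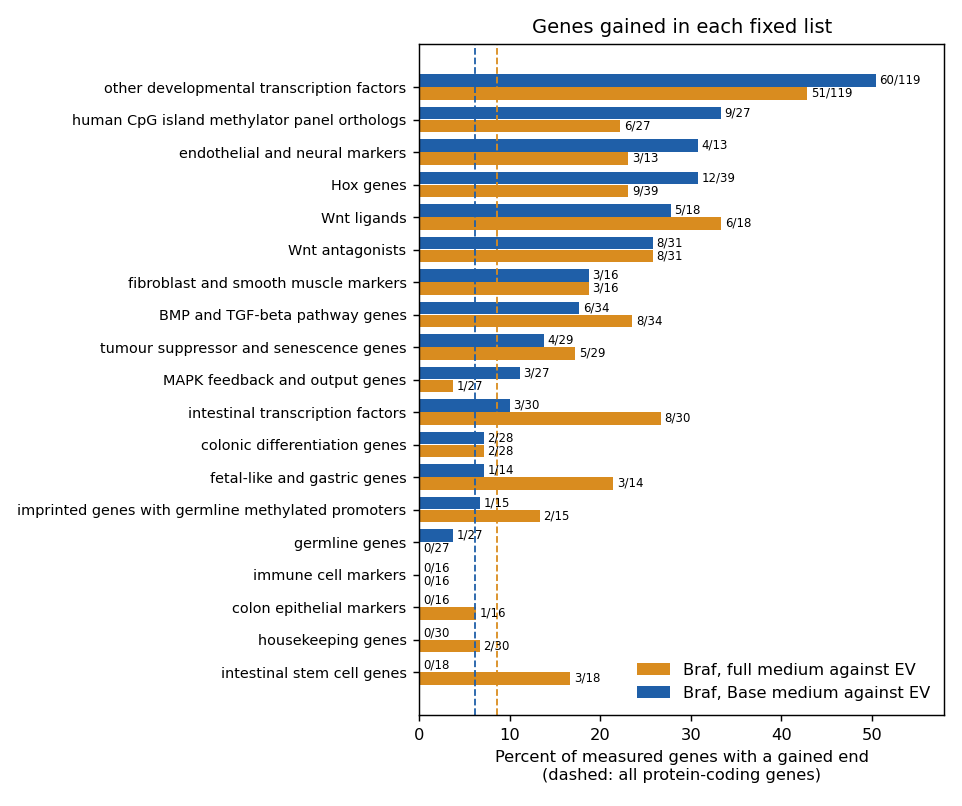
Percent of the measured genes of each fixed list with a gained end, in Braf full medium against EV and in Braf Base medium against EV, with counts at the bars; dashed lines give the percent over all protein-coding genes, 8.55% and 6.19%. Developmental transcription factors outside the Hox clusters reached 42.9% and 50.4%, and immune markers 0% in both.

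Of 30 intestinal transcription factors 3 gained, Cdx1 (0 to 0.741), Gata5 (0.0821 to 0.424) and Foxa3 (0.484 to 1.09), and Klf5 was lost (1.39 to 0.640); Klf5 lies at 99.3 Mb on chromosome 14, in the segment of low background, and its log2 ratio of -1.05 became -0.30 with local dosage divided out. Of 28 colonic differentiation genes Chgb (0 to 0.269) and Car4 (0.0365 to 0.242) gained and Cdhr5 (0.899 to 0.340) was lost. Of 18 stem cell genes Hopx alone was called (0.224 to 0.0135, lost). Of 14 fetal-like and gastric genes Sox2 gained (0.132 to 0.404) and 1 was lost. Of 27 MAPK genes 3 gained, Dusp2 (0 to 0.229), Egr2 (0.0274 to 0.128) and Spry4 (0.114 to 0.290). No MAPK gene gained with a minimum of 5 times the mean, a pseudocount 4 times as large or the mean over both ends, where the Wnt ligands gained were 1, 1 and 2. No housekeeping gene and no epithelial or immune marker was called; with an equal median of covered windows, and also with equal totals, 1 epithelial marker was lost.

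Of 29 tumour suppressor and senescence genes 4 gained and 0 lost: Dapk1 (0.648 to 3.50), Igfbp7, a secreted mediator of oncogene-induced senescence (0.648 to 1.78 at its high end), Timp3 (0.780 to 1.95) and Cdkn2a (0.0730 to 0.239 at its high end). The low end of Cdkn2a had 0.0183 in EV and 0.0909 in Base medium, below the minimum, and its log2 ratio of 0.95 became 1.16 with equal totals. Sfrp4 gained at its low end, from 0.00913 to 0.192 (21.0-fold, 95% interval 2.76 to 699). Cdx2 had no overlap at either end in either library, and Braf had at most 0.0135. Of 15 imprinted genes Grb10 gained (0.219 to 3.13). Of 27 germline genes Rnf17 gained (0.137 to 0.404), and Piwil1 (0.634 to 0.138) and Tex14 (1.51 to 0.593) were lost. Among markers of other cells, Zeb2 (0 to 0.246), Vim (0.0319 to 0.283) and Des (0.178 to 0.478) gained and Col1a1 (0.397 to 0.00674) was lost, and Sox10 (0.0228 to 0.573), Kdr (0.0137 to 0.478), Elavl4 (0.246 to 0.677) and Elavl3 (0.246 to 0.616) gained.

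Of the genes gained against EV, 829 were gained in both media, 46.9% of those in full medium and 64.8% of those in Base medium; independent lists would share 109.3 and simulated libraries without differences shared a median of 9.5. Of the genes lost, 147 were lost in both, against 6.12 for independent lists and 0 simulated. The comparisons share the EV library, which cannot be split, so part of the excess may come from it and 109.3 and 6.12 are no baselines. The simulated overlaps were bounded by short lists. Simulated libraries gave medians of 15 genes gained in Base medium and 1 lost in full medium, each against EV. Of the 1279 genes gained in Base medium against EV, 367 were also gained against Braf full medium. Independent lists would share 25.8, but both comparisons share the Base medium library, so that value is no baseline. Simulated libraries shared 0, which follows from their median of 0 genes gained against full medium.

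By genomic class, coverage in Base medium against EV was higher at gene ends (log2 ratio of the means 0.37) and lower outside genes (-0.34); with equal totals the values were 0.56 and -0.15. Gene bodies were at -0.09, and at 0.11 with equal totals. In 1-kb tiles, 2439 gained and 1584 lost at gene ends, and 1188 gained and 13229 lost outside genes. Braf full medium against EV stood at 0.67 at gene ends, 0.72 in gene bodies and 0.70 outside genes, and at -0.032, 0.011 and -0.0048 with equal totals.

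Background coverage, read from bins with few overlaps, was also compared along the chromosomes; whether it follows DNA dosage was not tested. In Base medium against EV, the 22 segments of chromosome 3 from 50 Mb on had a median log2 ratio of 0.50 and the 10 before them 0.00. The 10 segments of chromosome 14 from 75 Mb on had a median of -0.84, 0.559-fold, and the 15 before them -0.14. Of the 111 genes on that part of chromosome 14, 4 gained and 16 lost, and of the 837 on that part of chromosome 3, 60 gained and 6 lost. With local dosage divided out, 1274 genes gained and 462 lost over all chromosomes, of which 1235 and 440 were also called without it.

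**Figure D5:**
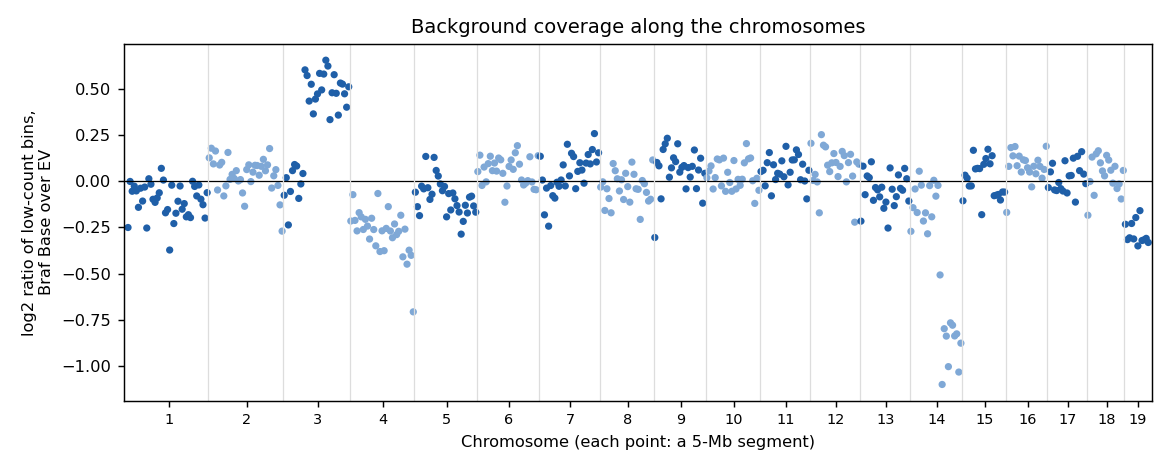
Log2 ratio of coverage in bins with few overlaps, Braf Base medium over EV, for each 5-Mb segment (points) along chromosomes 1 to 19. Segments of distal chromosome 3 lay between 0.33 and 0.66 and those of distal chromosome 14 between -1.10 and -0.77, and the median was -0.26 on chromosome 4 and -0.31 on chromosome 19.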

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

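Background subtraction, the 2 dosage settings, the mean over both gene ends, the limit on gene length and the counting intervals were chosen after seeing the data. No paired analysis was possible because each group held 1 library. Windows on CpG islands and at every transcript start were planned and not run, as the gene table used gives neither, and a setting of autosomes alone was void because the table analysed holds autosomes. In simulated data the calling step recovered 28% of 2-fold and 92% of 4-fold gains in Base medium against EV; the 2-fold gains had a median log2 ratio of 0.79, below the size rule. Depth was not varied, so its part in these limits was not separated from that of the rule and the pseudocount.

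The direction of the comparisons with the Braf full medium library turned with the scaling. With equal totals, Braf full medium against EV had 787 genes gained and 884 lost (47.1% of calls gained, 88.3% as deposited) and Base against full medium 1972 and 205 (90.6%, against 27.2%). Part of this follows from the construction, since the total includes background. With an equal median of covered windows the first had 398 lost (76.0% gained) and the second 676 lost (43.0%). With background subtracted the counts were 954 and 527, and 695 and 341. In Base medium against EV more genes were gained than lost under all alternatives run, with 1273 gained and 537 lost after background subtraction, of which 1253 and 525 were also called without it.

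Stricter settings lowered the counts by construction. In the order full medium against EV, Base against full medium, Base medium against EV, a pseudocount 4 times as large gave 591 gained and 66 lost, 239 and 119, and 787 and 127. A log2 ratio of 1.5 gave 1144 and 86, then 239 and 504, then 212 lost. A minimum of 5 times the mean gave 699 gained and 168 lost, then 352 and 222, then 893 and 272; simulated libraries without a difference in methylation gave medians of 28 and 0, 0 and 20, and 1.5 and 2. In Base against full medium the balance thus turned with this minimum and with the larger pseudocount. The mean over both gene ends gave 943 and 88, then 258 and 422, then 239 lost. With no minimum the first had 7624 gained and the second 6515 lost. The second had 1903 lost with a window of 500 bp and 1773 with local dosage divided out; the cause was not tested.

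By class, in Braf full medium against EV the log2 ratio with equal totals and with an equal median was -0.0048 and 0.41 outside genes, 0.011 and 0.42 in gene bodies, and -0.032 and 0.38 at gene ends. In Base against full medium it was -0.14 and -0.87 outside genes, 0.094 and -0.64 in gene bodies, and 0.59 and -0.14 at gene ends. In Base medium against EV it was -0.15 and -0.47 outside genes, 0.11 and -0.22 in gene bodies, and 0.56 and 0.24 at gene ends.

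Some list medians moved back within the limits of the random lists. These were germline genes in full medium against EV, and Wnt antagonists and imprinted genes in Base against full medium. In Base medium against EV they were BMP and TGF-beta genes and Wnt ligands. There BMP and TGF-beta genes fell from percentile 99.67 to 60.8 with 0.25 times the pseudocount and 61.88 with 500 bp. The other medians below moved beyond the limits. All list medians that crossed them, in either direction, are given next, and the cause was not tested. In full medium against EV these were immune markers with equal totals (0.33), germline genes with 0.25 times the pseudocount (0.59), intestinal transcription factors with 4 times the pseudocount (0.33) and with background subtracted (0.29), and Wnt ligands with 500 bp (1.03). In Base against full medium they were methylator panel orthologs with equal totals (0.11), an equal median (-0.22), 0.25 times the pseudocount (-0.66) and background subtracted (0.27), and Wnt antagonists with an equal median (-0.31), 4 times the pseudocount (-0.15), 500 bp (-0.38) and background subtracted (0.094). Hox genes followed with an equal median (-0.29), 0.25 times (-0.75) and 4 times (-0.14) the pseudocount, 500 bp (-0.33) and background subtracted (0.18). BMP and TGF-beta genes did so with 4 times the pseudocount (-0.14) and background subtracted (0.12), imprinted genes with 500 bp (-0.13), and immune markers with 500 bp (-0.39) and background subtracted (0.078). In Base medium against EV they were methylator panel orthologs with 0.25 times the pseudocount (0.39), 500 bp (0.20) and background subtracted (0.17), BMP and TGF-beta genes with the same settings (0.11, 0.033 and 0.090), Wnt antagonists with 500 bp (0.19) and background subtracted (0.16), and Wnt ligands with 500 bp (0.15). Developmental transcription factors outside the Hox clusters crossed no limit under the alternatives run.

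Genes gained per list varied over the alternatives run, leaving out the limit on gene length and the setting with no minimum. In full medium against EV, Base against full medium and Base medium against EV, developmental transcription factors outside the Hox clusters ranged from 22 to 57, 16 to 52 and 39 to 70, Hox genes from 6 to 10, 3 to 14 and 7 to 13, and methylator panel orthologs from 3 to 8, 3 to 8 and 6 to 10. Wnt antagonists ranged from 4 to 8, 1 to 7 and 6 to 8, BMP and TGF-beta genes from 3 to 9, 1 to 8 and 4 to 8, and Wnt ligands from 0 to 7, 0 to 3 and 1 to 5. Intestinal transcription factors ranged from 2 to 8, 0 to 3 and 2 to 6, tumour suppressor and senescence genes from 1 to 5, 0 to 6 and 1 to 5, colonic differentiation genes from 1 to 6, 0 to 3 and 0 to 4, and MAPK genes from 0 to 5, 0 to 2 and 0 to 3. In full medium against EV, stem cell genes and fetal-like and gastric genes both ranged from 0 to 3 and housekeeping genes from 0 to 5; the causes were not tested.

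Of the named gene ends with a call, 1 turned direction under the alternatives run, the low end of Alpi with 500 bp in full medium against EV, at -0.17; the cause was not tested. Ends without a call also changed sign in Base against full medium, such as the low end of Igfbp7 (-0.25, and 0.29 with background subtracted) and the high ends of Sfrp4 (-0.38 and 0.15) and Braf (-0.74 and 0.050). Of 238 named values, 26 lost their call with background subtracted, 35 with equal totals, 19 with an equal median, 34 with 500 bp and 10 with local dosage divided out. More did so with a pseudocount 4 times as large (76), a minimum of 5 times the mean (64), the mean over both gene ends (56), genes of at least 5 kb (51, partly by construction) and a log2 ratio of 1.5 (41). The low end of Sfrp4 in Base against full medium, at 0.99, reached the call with an equal median (1.09), 500 bp (1.33) and local dosage divided out (1.10), among others.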

Other observations

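The tests of stronger enrichment and of the distal parts of chromosomes 3 and 14 were chosen only after the result was seen. Of the 1766 genes gained in full medium against EV, 778 were called lost in Base against full medium. Independent lists would share 95.3, but both comparisons share the full medium library, so that value is no baseline. Simulated libraries without a difference in methylation shared a median of 965.5, more than the 778 seen. Slc22a21 rose from 0.0274 in EV to 1.74 in full medium and had no overlap in Base medium. Rb1, the retinoblastoma gene, chosen after its values were seen because it lies at 73.2 Mb on chromosome 14 where background coverage drops, had 2.51 in EV, 2.44 in full medium and 1.79 in Base medium at its low end.

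In Braf full medium against EV, genes gained outnumbered genes lost 7.55 to 1. With equal totals the ratio was 0.890, but that setting moves every bin of a library by 1 factor, so the turn is built in and the authors' scaling cannot be told apart as a source of the excess. With background subtracted it was 1.81, between the bounds set for that test, so a part from the higher background cannot be told apart from the rest. An effect of activated Braf stays open and was not tested, since each group is 1 library.

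In Base medium against EV, gene ends gained while DNA outside genes was lower. Of the gained genes, 13.7% lay on the 3 chromosomes with the highest background coverage, taken here as dosage, which hold 13.9% of all genes. Only chromosome 3 was clearly raised among them, at 1.28-fold, with chromosomes 9 and 16 at 1.03-fold and 1.04-fold. A rise of that size falls short of the size rule, so this test cannot decide on extra copies. With local dosage divided out, 1274 genes gained, 1235 of them also called without it. Gene ends covered in all libraries had a median log2 ratio of 0.15. These ends were already covered in EV, so the value cannot decide on stronger enrichment at ends that were not. Gained ends had 0.429 of the median coverage of ends covered in all libraries, between the bounds set, so a share of other cells cannot be told apart. Among tiles covered in all libraries, gene ends exceeded tiles outside genes by 0.615 of the difference between the classes, so a different recovery of DNA classes may account for the class shift. Braf and the medium stay open as untested explanations.

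Background coverage, relative to that of all segments, shifted along some chromosomes. On chromosome 19, 100% of segments were higher in EV than in full medium by a log2 ratio of at least 0.2 (median 1.36-fold). In Base medium 58.3% were higher than in full medium by that limit (median 1.17-fold), and 83.3% were lower than in EV (median 0.806-fold). Which library holds the shift cannot be told from 1 library per group. By the same limit, in Base medium against full medium 56.25% of segments on chromosome 3 were higher. On chromosome 14, 68% were lower and all lay below 0, the highest at -0.011. A copy number change of the whole of chromosome 19 cannot be told apart from other sources of its shift. On chromosomes 3 and 14 the shifts against EV were uneven. The 10 segments of chromosome 3 before 50 Mb lay between -0.24 and 0.091, and the 22 from there between 0.33 and 0.66. The 15 segments of chromosome 14 before 75 Mb lay between -0.51 and 0.054, and the 10 from there between -1.10 and -0.77. An even change of the whole of either chromosome would not alone give such a difference, if background follows dosage. Against EV, covered tiles on distal chromosome 3 were at 0.23 where the background shift was 0.50, and those on distal chromosome 14 at -0.34 where it was -0.84. Both fell short of the background, on chromosome 3 within the limit set for a copy gain and on chromosome 14 outside that for a copy loss. The limits were set after the result was seen. A gained or lost copy of these segments thus cannot be told apart from other sources of the shifted background.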
